A study of Mus musculus with 4 samples.

How the data were processed

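ATAC-seq libraries of mouse heart at postnatal day 14 were compared between 2 wild-type and 2 Carm1 mutant samples; the labels give the age as a postnatal day, and the series' design text calls the hearts neonatal. Per the labels, a commercial provider prepared the libraries. The submitters' processing notes name FastQC and Bowtie2, without versions, and the mouse genome build mm10. The peak caller, the read filters, the handling of duplicate reads, any shift of reads for the transposase and the way the common peak set was made are not given in the sources used here, and each could change which regions were counted and how strongly. The authors deposited 1 table of raw counts per peak for the 4 libraries, with whole-number counts and no normalization, per the file headers and the values. Each column name matched the title of 1 sample.

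The table held 87948 peaks with a median width of 533 bp, 63.6 Mb in all. Total counts in peaks lay between 15945420 and 19091969 per library, and the median count per peak lay between 90 and 106. Reads outside peaks were not analysed here, so the share of reads in peaks is unknown. Replicates of a genotype differed by more than sampling noise (chi-square per degree of freedom of 4.09 in the wild type and 5.76 in the mutant), so each library counted as 1 replicate.

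Peaks were tied to genes with a RefSeq gene table of assembly GRCm38.p6, the same assembly as mm10. As a check of the coordinates, 18.23% of peaks lay within 1 kb of a protein-coding gene end, against 5.73% after all peaks were moved by 1 Mb. The table gave gene ends without strand or exons. Either end of a gene therefore stood in for the transcription start site that had been planned, and no peak could be placed in an exon, intron or UTR. A peak within 1 kb of a gene end belonged to that gene (gene-end peak), and any other peak to the protein-coding gene with the nearest end within 50 kb; 67905 peaks had a gene. A peak was called "within" a gene where its midpoint lay between the gene's ends.

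Peaks were compared with edgeR 4.0.16 in R 4.3.3 (quasi-likelihood test, genotype as the only term, TMM normalization, filterByExpr, Benjamini-Hochberg adjusted p under 0.05). The filter removed 0 peaks. CPM values are counts scaled by TMM-adjusted library sizes, and log2 CPM for the scores and correlations used a prior count of 1. Log2 fold changes are mutant over wild type, with standard errors derived from the test statistic. The common biological coefficient of variation was 0.166, with 2 residual degrees of freedom per peak. Gene lists were tested with camera and fry of limma 3.58.1, camera with a preset correlation of 0.01, on lists with 5 or more peaks. The estimated correlation was 0.31 for endothelial, 0.22 for mature contractile, 0.2 for fatty acid oxidation and 0.11 for ion channel peaks. It was 0.04 for fetal contractile and 0.0024 for Schwann and neuronal peaks. Where the estimate exceeds the preset, p-values at the preset may be too small. The 25 lists, with 525 entries of which 520 matched a symbol of the RefSeq table, were fixed before the data were examined, as were the main tests, the alternatives unless said otherwise, and the rule for naming peaks. Several lists share cell types: many genes of the contractile, fatty acid oxidation and ion channel lists are active in cardiomyocytes.

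The named peaks were all peaks in or within 5 kb of Carm1; the 10 higher and 10 lower peaks with the smallest p among called peaks in which both mutant libraries lay on the same side of both wild-type libraries, at most 1 per gene; the 3 peaks with the smallest p in the direction of each list past the threshold, and the 2 with the smallest p of the contractile, fatty acid oxidation and cell cycle lists; and the strongest gene-end peak of Myh6, Myh7, Tnni3, Tnni1, Nppa, Nppb, Ppargc1a and Cdkn1a.

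The procedure was tested on simulated counts for this comparison of 2 against 2 over 87948 peaks. In it 67, 67 and 66 peaks were changed by folds of 1.5, 2 and 3, and 87748 were left unchanged. It recovered 6.0%, 40.3% and 87.9% of the changed peaks, with 5 false calls among 94. In the data 4839 peaks were called, so the cut-off on p was less strict than in the simulation and these shares need not hold there. Each simulated peak was drawn independently, with its dispersion set on the fitted trend and no shift shared within a library. The share of false calls is therefore no measure of error control in the data. Real differences under a fold of 2 may still be missed. Alternatives were other scalings (RLE, total counts, cyclic loess offsets), other filters, DESeq2 1.42.0, limma voom, a looser threshold, a test against a fold of 1.2, each library left out in turn, a replicate block, and other ways to assign peaks to genes or to test lists. The results of 1 item are not reported here by name. Motif sets and a correction for GC content need the genome sequence, which was not used here, and were not run. Peak assignment used Python 3.11.15 with pandas 2.3.3.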

Results

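Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open chromatin and inserts sequencing adapters, in hearts of mice at postnatal day 14. The libraries fell into 2 wild-type and 2 Carm1 mutant replicates. Carm1, also known as Prmt4, is an arginine methyltransferase that modifies histones and other proteins and acts as a transcriptional coactivator. The labels gave the tissue as heart and named no cell type, and heart tissue holds cardiomyocytes together with endothelial cells, fibroblasts, mural cells and immune cells. The series concerned how this enzyme acts on chromatin while the heart matures, and the comparison asked which regions differed in accessibility between the genotypes. The deposited table held read counts in 87948 peaks, with total counts in peaks of 17508230 and 19091969 in wild-type replicates 1 and 2 and of 16740589 and 15945420 in mutant replicates 1 and 2. The labels did not describe how animals were assigned to replicates. The 2 libraries of each genotype differed in Y-linked counts, given with the sex chromosomes, so they did not come from the same animal, and the spread behind the p-values includes that difference.

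The Carm1 gene itself was examined first. The strongest peak at the locus, at the lower-coordinate end of Carm1 (chromosome 9, 21545484 to 21546896, mm10), had 89.8 ± 0.38 CPM (counts scaled to the library size) in the wild type and 93.5 ± 2.86 in the mutant (SD, n = 2 each), a log2 fold change of 0.06 (SE 0.12, edgeR adjusted p = 0.839). Within the gene, a weak peak at 21574070 to 21574390 was lower in the mutant, at 1.24 ± 0.056 against 3.26 ± 0.13 CPM (SD, n = 2 each), a log2 fold change of -1.39 (SE 0.38, edgeR adjusted p = 0.0367). A weak peak at 21544727 to 21545162, at the neighbouring gene AB124611, was higher, with a log2 fold change of 1.38 (SE 0.37, edgeR adjusted p = 0.035). The other 7 of the 9 peaks in or within 5 kb of Carm1 did not pass the threshold, and their log2 fold changes lay between 0.05 and 0.70. The labels did not give the altered part of the gene, so the peak at the gene end does not check the genotype labels. The call within Carm1 was lost without wild-type replicate 1 (edgeR adjusted p = 0.131), wild-type replicate 2 (0.211) or mutant replicate 2 (0.0531), and that at AB124611 without wild-type replicate 1 (0.218), wild-type replicate 2 (0.0842) or mutant replicate 1 (0.137). Neither passed with DESeq2 (adjusted p = 0.135 and 0.102) or limma voom (0.0602 and 0.052), and the peak within Carm1 did not pass with trended offsets (0.0799).

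**Figure D1:**
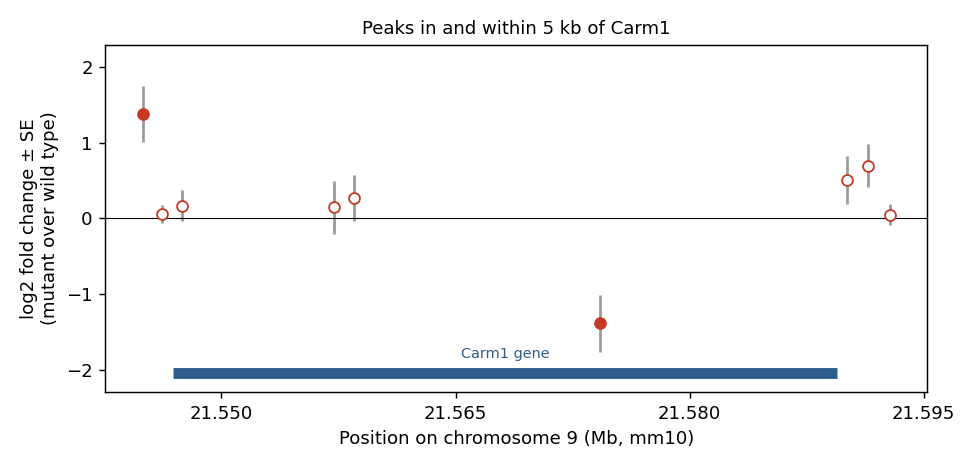
Log2 fold change of mutant over wild type, with its standard error, for the 9 peaks in and within 5 kb of Carm1, against position on chromosome 9 in Mb. Filled points passed an edgeR adjusted p of 0.05, 1 higher and 1 lower, the bar marks the Carm1 gene, and the peak at its lower-coordinate end lies at 0.06.

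Accessibility differed between the genotypes in both directions. Of the 87948 peaks, 2683 were higher and 2156 lower in the mutant heart, with a median fold of 2.32 among the higher and 2.27 among the lower peaks. At least 1 higher peak was assigned to 1599 genes and at least 1 lower peak to 1079 genes, with 112 genes in both groups. The first principal component, with 58.7% of the variance, separated the genotypes, and libraries of a genotype correlated more closely across peaks (Pearson's r of 0.958 in the wild type and 0.942 in the mutant) than libraries of different genotypes (0.899 to 0.91). Peaks are not independent replicates, so these correlations carry no test. Calls were made with edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, and DESeq2 called 1365 higher and 1008 lower peaks. With edgeR and scaling by total counts, 2419 were higher and 2570 lower, so the excess of higher peaks depended on the scaling. The number of calls fell without either wild-type library and rose without either mutant library. Such a fit leaves a lone library in a genotype and takes the spread from the other genotype's pair. A call lost in such a fit, here or at a named peak, can reflect a changed spread as well as a changed fold. There were 1028 higher and 882 lower peaks without wild-type replicate 1, 642 and 364 without wild-type replicate 2, 4204 and 2737 without mutant replicate 1, and 4307 and 4132 without mutant replicate 2. In all, 318 higher and 187 lower peaks were called with all libraries and also whichever library was left out.

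Among the higher peaks with the smallest p-values, a peak within Fig4, which encodes a phosphoinositide phosphatase (chromosome 10, 41292786 to 41294020), rose from 13.5 ± 1.14 to 45.3 ± 0.52 CPM (SD, n = 2 each), a log2 fold change of 1.74 (SE 0.16, edgeR adjusted p = 2.86e-05). A peak within Fgf18, a fibroblast growth factor gene (chromosome 11, 33142681 to 33143579), rose from 3.55 ± 0.50 to 15.8 ± 2.48 CPM. A peak within Rab20, a gene of endosomal traffic (chromosome 8, 11457263 to 11458319), rose from 8.05 ± 1.82 to 29.3 ± 7.12 CPM. A peak 48739 bp from the nearest end of Tpra1 (chromosome 6, 88960979 to 88961287) rose from 0.60 ± 0.53 to 10.4 ± 4.34 CPM, a log2 fold change of 4.07 (SE 0.44; 3.40 without wild-type replicate 1 and 5.48 without wild-type replicate 2). The other 6 of the 10 higher peaks lay at Ankrd1, near Vdac3, at the lncRNA gene Gm31588, within Ripor2 and, for 2 of them, 324974 and 337837 bp from the nearest protein-coding gene end. Their log2 fold changes were from 1.28 to 2.74. Among the lower peaks, a peak 4451 bp from Cyb5a, which encodes cytochrome b5 (chromosome 18, 84884322 to 84885641), fell from 27.7 ± 1.07 to 4.82 ± 1.31 CPM, a log2 fold change of -2.52 (SE 0.22, edgeR adjusted p = 1.91e-05). A peak within Shld1, a gene of DNA double-strand break repair (chromosome 2, 132689162 to 132690352), fell from 67.2 ± 9.41 to 21.8 ± 1.18 CPM. A peak within Bcl9, a gene of the Wnt pathway (chromosome 3, 97267479 to 97267797), fell to 0.74 ± 0.24 CPM, a log2 fold change of -3.22 (SE 0.37). A peak near its paralog Bcl9l (chromosome 9, 44474216 to 44474868) fell from 13.9 ± 0.70 to 3.17 ± 1.05 CPM. A peak within Cacnb2, which encodes a calcium channel subunit (chromosome 2, 14936363 to 14936977), fell from 31.9 ± 3.88 to 7.56 ± 2.52 CPM. The other 5 lower peaks lay within Fnip2, Tnik, Map3k20 and Smg1 and near Prr30, with log2 fold changes from -2.82 to -1.48. The value of -2.82, at Prr30, was -2.21 without wild-type replicate 2 and -3.46 without mutant replicate 2.

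Several genes carried clusters of higher peaks, chosen here after their values were seen. Lbh, a transcription cofactor gene of the embryonic limb bud and heart, had 11 of its 24 peaks past the threshold, all higher, with log2 fold changes from 0.65 to 1.81. Pdk4, which encodes the kinase that restrains pyruvate oxidation, had 7 of 11, with log2 fold changes from 0.64 to 1.71. Ankrd1, a stress-responsive sarcomere gene, had 5 of 11, from 1.14 to 1.99, and its gene-end peak (chromosome 19, 36118903 to 36120686) reached 40.3 ± 0.80 CPM in the mutant (SD, n = 2; log2 fold change 1.53, SE 0.18, edgeR adjusted p = 2e-04). Myocd, which encodes the muscle coactivator myocardin, had 6 of 37, and Amotl2 had 5 of 19. In the fit behind these counts none of the 5 genes had a lower peak past the threshold, and without mutant replicate 2 Pdk4 had 1. When any 1 library was left out, Pdk4 held 5 to 7 and Ankrd1 4 to 8 higher calls. Without wild-type replicate 2, Lbh, Amotl2 and Myocd held 1, 1 and 0, and without wild-type replicate 1 they held 6, 3 and 3. Myocd had 1 without mutant replicate 1.

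**Figure D2:**
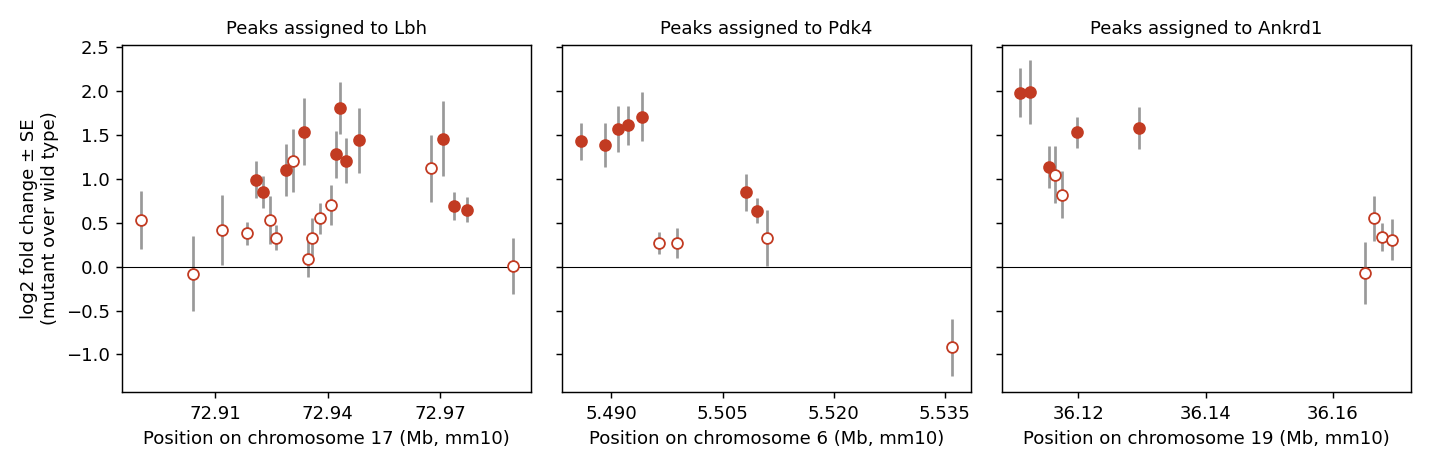
Log2 fold change of mutant over wild type, with its standard error, for every peak assigned to Lbh, Pdk4 and Ankrd1, against position in Mb. Filled points passed an edgeR adjusted p of 0.05, and all 11, 7 and 5 of them lie above 0.

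By camera at its preset correlation only, peaks near fetal contractile and stress genes were shifted upward in the mutant. The heart uses this set of genes before birth and again under load. Of 102 peaks near 17 of the 18 listed genes, 14 rose, 1 fell and 87 did not pass the threshold (23 rose and 1 fell when adjusted over the list alone), and the median log2 fold change was 0.31. The 14 higher peaks lay at 9 genes, 5 of them at Ankrd1. The rise also included a peak 22755 bp from Xirp2, which encodes a protein of the intercalated disc (chromosome 2, 67422851 to 67423245), at 1.57 ± 0.026 CPM in the wild type and 8.33 ± 2.68 in the mutant (SD, n = 2 each; log2 fold change 2.41, SE 0.33, edgeR adjusted p = 0.000522). It was the only called peak of the 6 assigned to Xirp2, whose median log2 fold change was -0.08. The peak near Nppa, which encodes atrial natriuretic peptide (chromosome 4, starting at 148000000), rose from 2.40 ± 0.84 to 5.40 ± 1.02 CPM (log2 fold change 1.16, SE 0.33, edgeR adjusted p = 0.0444), and that call was lost without wild-type replicate 1 (0.313), wild-type replicate 2 (0.0656) or mutant replicate 2 (0.105). It was also lost with DESeq2 (adjusted p = 0.121), limma voom (0.052), total counts (0.0503) and a mean CPM of at least 2 (0.0506). The strongest gene-end peaks of Nppb, Myh7 and Tnni1 did not pass the threshold, with log2 fold changes of 0.47, 0.39 and 0.49 (edgeR adjusted p = 0.145, 0.154 and 0.264), while 2 of 4, 1 of 14 and 1 of 10 peaks of these genes were called higher. That of Nppb passed without mutant replicate 1 (0.00361) and that of Myh7 without wild-type replicate 1 (0.0312) or mutant replicate 2 (0.0049). By camera with a preset correlation of 0.01 the list stood apart from other peaks at adjusted p = 6.5e-07, and it stayed past the threshold when any 1 library was left out. It had adjusted p = 0.877 with an estimated correlation and 0.285 by fry.

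Peaks near mature contractile genes, which encode the adult sarcomere, were shifted upward as well, again only at the preset correlation. Of 310 peaks near 23 genes, 23 rose at 9 genes and 3 fell at 2 genes, while 284 did not pass the threshold (39 rose and 4 fell when adjusted over the list alone), and the median log2 fold change was 0.25. A peak within Tpm1, the tropomyosin gene (chromosome 9, 67025335 to 67027143), rose from 22.5 ± 0.14 to 43.0 ± 10.3 CPM (SD, n = 2 each; log2 fold change 0.94, SE 0.17, edgeR adjusted p = 0.00426). Peaks also rose at Ldb3, Myom2 (4 each), Myoz2 and Tnnt2 (3 each). Actc1, which encodes cardiac alpha-actin, went the other way: its gene-end peak (chromosome 2, 114046828 to 114048615) fell from 30.5 ± 9.70 to 13.7 ± 0.57 CPM (log2 fold change -1.16, SE 0.20, edgeR adjusted p = 0.00336; 0.141 without wild-type replicate 2). The gene-end peaks of Myh6 and Tnni3, at 273 and 94.4 CPM in the wild type, had log2 fold changes of 0.21 and 0.23 that did not pass the threshold (edgeR adjusted p = 0.245 and 0.333), although that of Tnni3 passed without mutant replicate 2 (0.0235). Camera gave the list adjusted p = 3.3e-05, with 0.877 with an estimated correlation and 0.464 by fry. Without mutant replicate 1 the median log2 fold change was 0.08 and the camera adjusted p was 0.165. Without wild-type replicate 2 the median was 0.16.

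Peaks near genes of fatty acid oxidation were shifted upward at the preset correlation only, with Pdk4 supplying most of the higher calls. Of 173 peaks near 28 genes, 11 rose, 5 fell and 157 did not pass the threshold (14 rose and 6 fell when adjusted over the list alone), and the median log2 fold change was 0.19. Of the 11, 7 lay at Pdk4, whose product limits glucose oxidation and is not an enzyme of fatty acid oxidation itself, and 1 each at Acadl, Acsl1, Lpl and Ucp3. The Pdk4 peak with the smallest p (chromosome 6, 5491449 to 5492923) rose from 6.83 ± 0.052 to 20.8 ± 5.37 CPM (SD, n = 2 each; log2 fold change 1.61, SE 0.22, edgeR adjusted p = 0.000608). The 5 lower peaks lay at Cd36, a gene of fatty acid uptake, and Lpl, the lipoprotein lipase gene (2 each), and at Decr1. Camera gave adjusted p = 0.00178, with 0.877 with an estimated correlation and 0.464 by fry, and 0.364 without mutant replicate 1. The median was 0.07 without mutant replicate 1 and 0.30 without mutant replicate 2. Peaks near genes of the TCA cycle and oxidative phosphorylation (145 peaks, median log2 fold change 0.05, 3 higher and 1 lower) and of glycolysis (132 peaks, median 0, 1 higher) were not shifted past the threshold, at camera adjusted p = 0.695 and 0.886.

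Peaks near genes of ion channels and gap junctions, which carry the cardiac action potential, were shifted upward at the preset correlation only. Of 196 peaks near 23 genes, 17 rose at 11 genes, 4 fell at 4 genes and 175 did not pass the threshold (26 rose and 5 fell when adjusted over the list alone), and the median log2 fold change was 0.19. The rise included the gene-end peak of Hcn2, a pacemaker channel gene (chromosome 10, 79715002 to 79718695), at 22.6 ± 6.16 and 43.1 ± 9.18 CPM (SD, n = 2 each; log2 fold change 0.93, SE 0.19, edgeR adjusted p = 0.00744; 0.172 without wild-type replicate 2). Peaks at Kcnq1 and Cacna1h rose by 1.12 and 1.78 on the log2 scale, and both calls were lost without wild-type replicate 2 (edgeR adjusted p = 0.11 and 0.188), that of Kcnq1 also without wild-type replicate 1 (0.0716) and that of Cacna1h with DESeq2 (0.0597). The 4 lower peaks lay at the potassium channel genes Kcna5, Kcnd3, Kcnj2 and Kcnj5. Camera gave adjusted p = 0.00317, with 0.877 with an estimated correlation and 0.464 by fry, 0.0512 without wild-type replicate 2 and 0.364 without mutant replicate 1. The median was 0.12 without mutant replicate 1 and 0.30 without mutant replicate 2.

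Peaks near endothelial marker genes were shifted downward at the preset correlation only. Of 190 peaks near 22 genes, 9 fell at 7 genes, 2 rose and 179 did not pass the threshold (11 fell and 3 rose when adjusted over the list alone), and the median log2 fold change was -0.20. The 2 that rose were assigned to Emcn and Flt1, that of Flt1 by 2.06 on the log2 scale. A peak 46397 bp from Sox17, an endothelial transcription factor gene (chromosome 1, 4543823 to 4544535), fell from 26.4 ± 9.51 to 9.19 ± 1.90 CPM (SD, n = 2 each; log2 fold change -1.52, SE 0.23, edgeR adjusted p = 0.00137). Peaks within Erg and Flt1 fell by 1.06 and 1.03 on the log2 scale, calls that were lost without wild-type replicate 1 for Erg (edgeR adjusted p = 0.0693) and without wild-type replicate 2 for Flt1 (0.138). Camera gave adjusted p = 0.00178, with 0.877 with an estimated correlation, 0.575 by fry and 0.209 on gene-end peaks only. Wild-type replicate 1 stood apart in this list, with a median centred log2 CPM of 0.256 against -0.076 in wild-type replicate 2 and -0.11 and -0.077 in the mutant libraries, and without it the median log2 fold change was 0 (camera adjusted p = 0.772). Without wild-type replicate 2 the median was -0.36. Between the genotype means the endothelial score was lower and the scores of the contractile, fatty acid oxidation and ion channel lists were higher. Within the wild type these scores did not oppose each other. Replicate 1 lay above replicate 2 in the endothelial score and also in those lists, for example mature contractile genes (-0.021 against -0.172). Within the mutant, replicate 1 was lower in the endothelial score (-0.11 against -0.077) and higher in those lists. The fibroblast, mural and immune marker lists had medians of -0.03, 0.02 and 0.09 and did not pass the threshold (camera adjusted p = 0.56, 0.489 and 0.597), although the fibroblast list passed as lower without mutant replicate 2 (median -0.29, adjusted p = 0.00368) and had a median of 0.08 without mutant replicate 1.

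**Figure D3:**
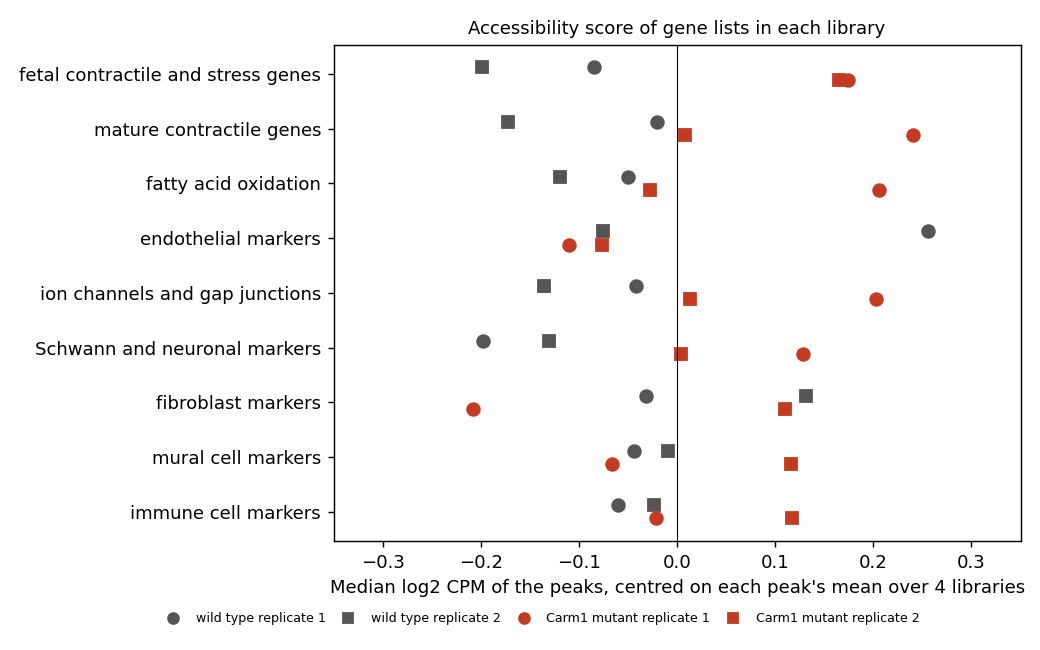
Median over a list's peaks of log2 CPM centred on each peak's mean over the 4 libraries, shown per library for the 6 lists past the camera threshold and for 3 further cell type lists. Circles are replicate 1 and squares replicate 2 of each genotype. In the 5 lists shifted upward both mutant libraries lie above both wild-type libraries. Those lists were called from the same libraries, so this separation is no further support. The immune list, which was not called, separates too, as do the housekeeping genes, not shown. At 51.5% of all peaks the genotypes did not overlap, in either direction. Wild-type replicate 1 stands apart in the endothelial list at 0.256.

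The last list past the threshold held Schwann cell and neuronal markers, with 4 of 26 peaks higher and 0 lower (5 higher and 0 lower when adjusted over the list alone) and a median log2 fold change of 0.27. The 4 peaks lay near Th, the tyrosine hydroxylase gene of sympathetic neurons, Kcna1, Nefl and S100b. The peak near Th (chromosome 7, 142929511 to 142930112) rose from 2.26 ± 0.39 to 9.19 ± 0.59 CPM (SD, n = 2 each; log2 fold change 2.02, SE 0.29, edgeR adjusted p = 0.000683), and it lay 29516 bp from the nearest end of that gene. The peak near Nefl lost its call without wild-type replicate 1 (edgeR adjusted p = 0.161) or mutant replicate 2 (0.247), and with DESeq2 (0.0819) or limma voom (0.0791). Camera gave adjusted p = 0.0133, with 0.877 with an estimated correlation and 0.285 by fry. On gene-end peaks only the camera adjusted p was 0.0862, and with genes within 10 kb it was 0.165. The call was also lost without wild-type replicate 1, where the median was 0.26, and without mutant replicate 1, where it was 0.15.

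The other lists did not pass the camera threshold. For cardiac transcription factors and coactivators, 12 of 422 peaks were higher, 6 of them at Myocd, and 6 were lower, with 2 at Esrrb (median log2 fold change 0.09, camera adjusted p = 0.129). Without mutant replicate 2 its median was 0.23 and passed (0.000184), and without mutant replicate 1 it was -0.04. This list passed on gene-end peaks only (median 0.22, camera adjusted p = 0.00203) and with genes within 10 kb (median 0.17, camera adjusted p = 0.00265). For fibrosis and matrix remodelling, 10 of 165 peaks were higher and 2 lower, and 3 of the 10 lay at Ccn2, a matricellular gene (median 0.08, adjusted p = 0.11; 0.0283 without mutant replicate 1, 0.0281 on gene-end peaks only and 0.0494 with 1 peak per gene). Its median was 0.15 without mutant replicate 1 and 0.02 without mutant replicate 2. For calcium handling and T-tubules, 6 of 258 peaks were higher, with 2 each at Camk2b and Camk2d, and 5 were lower, with 2 at Ryr2, the calcium release channel gene (median -0.05, adjusted p = 0.788). For the cell cycle, 2 of 76 peaks were higher, near Ccnd1 and E2f1 (median 0.08, adjusted p = 0.102; 0.0335 without wild-type replicate 2). Its median was 0.20 without wild-type replicate 2 and 0.03 without wild-type replicate 1. The Ccnd1 peak lost its call without mutant replicate 2 (edgeR adjusted p = 0.313), and the E2f1 peak without wild-type replicate 1 (0.168), wild-type replicate 2 (0.0693) or mutant replicate 2 (0.0559). With DESeq2 neither passed (adjusted p = 0.285 and 0.0816), and Ccnd1 did not with limma voom (0.0508). Skeletal muscle markers had a median of 0.26 over 21 peaks with 0 past the edgeR threshold over all peaks (6 higher and 1 lower when adjusted over the list alone; camera adjusted p = 0.102, 0.0465 without wild-type replicate 2 and 0.0245 with 1 peak per gene). Their median was 0.42 without wild-type replicate 2 and 0.13 without wild-type replicate 1. The lists of housekeeping genes, integrated stress response, erythroid markers, lung markers, p53 targets, epicardial markers, immediate early genes, atrial markers, and arginine methyltransferases with Carm1 substrates had medians between -0.06 and 0.1 and camera adjusted p from 0.218 to 0.999. In the epicardial list the median was -0.01 and the mean 0.13, and in the list of arginine methyltransferases the camera direction was downward with a median of 0.03. The strongest gene-end peak of Ppargc1a, a regulator of mitochondrial genes, had a log2 fold change of 0.34 (edgeR adjusted p = 0.38), and Cdkn1a had no peak within 1 kb of either end.

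Gene-end peaks and other peaks were compared as classes. Of 20363 peaks within 1 kb of either end of a gene, 395 (1.94%) were higher and 151 (0.74%) lower in the mutant. Of the other 67585 peaks, 2288 (3.39%) were higher and 2005 (2.97%) lower. The median log2 fold change was 0.037 at gene ends and -0.021 elsewhere, a gap of 0.058 that did not pass the threshold by camera (adjusted p = 0.139, and adjusted p = 0.423 with an estimated correlation; the family is 1 set, so adjustment leaves p as it is). The gap was 0.121 without mutant replicate 2 (camera adjusted p = 0.0106) and 0.00253 without mutant replicate 1 (camera adjusted p = 0.981).

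On the sex chromosomes, the 1311 peaks of chromosome X had a median log2 fold change of -0.005, with 41 higher and 32 lower. Of the 25 peaks of chromosome Y, 10 were higher and 0 lower, with a median of 1. Those 10 lay among 11 peaks at 90738838 to 90810456, near the end of chromosome Y, whose summed CPM was 29.4 and 43.6 in wild-type replicates 1 and 2 and 93.9 and 93.3 in mutant replicates 1 and 2. Without wild-type replicate 1 and without wild-type replicate 2, 4 and 5 of the 11 passed the threshold. The Y-linked genes Uty and Ddx3y had peaks with 273 and 197 counts in wild-type replicate 1 and 251 and 201 counts in mutant replicate 1, and 0 counts in replicate 2 of both genotypes. Replicate 2 of both genotypes nonetheless had signal at the 11 peaks, so that signal did not follow Uty and Ddx3y. The median of 1 therefore cannot be read as a gain specific to chromosome Y. The labels did not give the sex of the animals. The counts at Uty and Ddx3y go with male tissue in replicate 1 of each genotype and with none in replicate 2. The replicates of a genotype thus appear to differ in sex, and the main fit has no term for that.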

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

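The merging of called peaks into regions, the assignment of peaks by gene body and the use of 1 peak per gene were chosen after seeing the data. Scaling changed the counts of higher and lower peaks by less than 1.5 times, with 2728 higher and 2197 lower peaks with DESeq2's size factors, 2419 and 2570 with total counts and 3281 and 2176 with trended offsets, and the median log2 fold change of all peaks stayed between -0.036 and 0.002. Removal of chromosomes X and Y (2725 and 2210), limma voom (2092 and 1615), a mean CPM of at least 2 (2273 and 1891) and merging within 10 kb (2346 and 2019 regions) also stayed within that range. Higher peaks made up 55.4% of calls in the main fit, 48.5% with total counts and 60.1% with trended offsets. Which direction held more calls thus depended on the scaling. The planned run without a filter was void because the filter removed 0 peaks, and the motif sets and the correction for GC content were not run. With total counts the medians of chromosomes X and Y moved by less than the spread between libraries. DESeq2 called 1365 higher and 1008 lower peaks, all 2373 among the main calls and in the same direction. A test against a fold of 1.2 left 1344 and 1016, and an adjusted p under 0.10 gave 4824 and 4127; both follow from their construction. When 1 library was left out, the higher peaks ranged from 642 to 4307 and the lower from 364 to 4132, the calls at the Carm1 locus from 0 to 1, the lists past the threshold from 3 to 8, and the gap between gene-end and other medians from 0.00253 to 0.121, past the camera threshold only without mutant replicate 2. In these fits the lone library of a genotype is assumed to vary like the other genotype's, and the cause of the changes was not tested. With trended offsets 1 peak at the Carm1 locus passed (the cause was not tested). With camera's estimated correlation and with fry, 0 lists passed, and 0 and 4 lists had an unadjusted p under 0.05.

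The labels name no litter or day behind the replicate numbers, and 2 pairs are too few to establish a pairing from the data. The numbers do coincide with signal at the Y-linked genes Uty and Ddx3y (present in replicate 1 and at 0 counts in replicate 2 of both genotypes). A replicate block therefore also takes up that difference. Deviations from the genotype means correlated at 0.108 across peaks for libraries of the same number, and 0.0914 without chromosomes X and Y. With the replicate block, 5230 peaks were higher and 4494 lower, 2 peaks at the Carm1 locus and 6 lists passed, and all 4839 main calls were kept. Among the named peaks, the block added calls at Myh7 (edgeR adjusted p = 0.00952) and Nppb (0.0287). With it Pdk4 also had 1 lower peak past the threshold.

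The 56 named peaks gave 614 values under 11 alternatives, the void run left out, of which 568 stayed on their side of the threshold, 40 lost the call and 6 gained one, with 0 turned values among peaks called in either fit. Of the 43 called named peaks, 28 were called under each of those alternatives, among them all 20 with the smallest p. The 6 lists gave 84 values, 60 of them past the threshold in the same direction, and other lists passed in 10 cases. Besides the losses with an estimated correlation, fry or a library left out, the endothelial and Schwann and neuronal lists missed the threshold with gene-end peaks only (camera adjusted p = 0.209 and 0.0862) and with genes within 10 kb (0.0584 and 0.165), and the ion channel list with 1 peak per gene (0.129). In the lowest of 10 equal abundance classes of peaks, with a mean of 2.04 CPM, 319 peaks were higher and 337 lower and the median log2 fold change was -0.355. In the highest class, 240 were higher and 88 lower and the median was 0.015. What depth limits was not tested apart from abundance.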

Other observations

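The tests of the share of cardiomyocyte nuclei, of the start of chromosome 3 and of other splits of the libraries were written only after the result they bear on was seen. Clusters of lower peaks at genes outside the fixed lists are named here after their values were seen. Susd6 had 5 of 33 peaks lower, and Plpp3, which encodes a lipid phosphate phosphatase, Pitpnc1, a phosphatidylinositol transfer protein gene, and Pirt had 4 of 19, 4 of 13 and 4 of 9. The log2 fold changes of these peaks lay between -1.76 and -0.63, and without wild-type replicate 2 the 4 genes held 0, 0, 1 and 0 calls. Without wild-type replicate 1 they held 1, 1, 1 and 2.

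Among genes known as targets of the YAP and TEAD transcription regulators, Ankrd1 and Amotl2 had 5 higher peaks each, Ccn2 and Ptpn14 had 3 each and Ccn1 had 1, with 0 lower. One hypothesis was that target genes of these regulators were more accessible as a group in the mutant. It was tested on the other 17 genes of a 22-gene list, whose 123 peaks had 5 higher and 2 lower calls and a median log2 fold change of 0 (95% gene bootstrap interval -0.146 to 0.159). Camera gave this set an adjusted p of 0.909, with 1 set in the family. The test thus gave no sign of a shift beyond the 5 genes that prompted it. The interval covers spread over genes and not between libraries, so an upward shift stays open and 0.159 is no bound on it.

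The lower endothelial and higher contractile scores may reflect differences in cell content. If mutant libraries held a larger share of cardiomyocyte nuclei, fibroblast, mural and immune peaks should fall as far as endothelial peaks; their pooled median lay 0.178 above the endothelial median (95% gene bootstrap interval 0.0711 to 0.307). The difference was 0.429 (0.305 to 0.565) without wild-type replicate 2 and 0.301 (0.149 to 0.447) without mutant replicate 1. It was -0.0452 (-0.197 to 0.106) without wild-type replicate 1 and 0.0625 (-0.074 to 0.194) without mutant replicate 2, so it depends on single libraries. Without wild-type replicate 1 the endothelial median was -0.00229. That fit held no endothelial fall to match, so its difference does not bear on the share. These intervals cover spread over genes and not between libraries. Schwann and neuronal markers, also outside muscle, went against a larger cardiomyocyte share, with a median 0.464 above the endothelial median (0.122 to 0.679). That difference was 0.266 (-0.00198 to 0.567) without wild-type replicate 1, an interval that reached 0, and it was 0.344 (0.023 to 0.651) without mutant replicate 1. The camera call of that list was also lost without either of those libraries, with medians of 0.263 and 0.152 against 0.268 with all libraries. It was lost as well with an estimated correlation (camera adjusted p = 0.877) and by fry (adjusted p = 0.285). Peaks near calcium handling and T-tubule genes, also active in cardiomyocytes, did not rise (median -0.05 over 258 peaks, 6 higher and 5 lower). Without wild-type replicate 1 the mature and fetal contractile medians were 0.33 and 0.35 although the endothelial median was 0. The fibroblast median was -0.15 in that fit, a fall that goes with a larger share. The lists thus point both ways, and a changed cardiomyocyte share and an effect of genotype cannot be told apart here. For the endothelial part, content that varied from library to library is a candidate explanation, since the gap between the wild-type libraries was 1.81 times the gap between the genotype means. The fetal contractile list stayed higher past the preset camera threshold without any 1 library, but not with an estimated correlation (camera adjusted p = 0.877) or by fry (adjusted p = 0.285). An effect of genotype on it stays open and was not tested apart from cell content.

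The start of chromosome 3 (3000231 to 3033637) held 21 peaks, of which 17 were higher in the mutant, with a median log2 fold change of 1.3. Summed CPM was 271.9 and 186.9 in wild-type replicates 1 and 2, and 324.2 and 822.9 in mutant replicates 1 and 2. Without mutant replicate 2 the median log2 fold change was 0.533, which is consistent with a feature of that library behind much of the shift. The number of calls does not single it out, since 4 peaks passed without mutant replicate 2 and 3 without wild-type replicate 2, where the median was 1.03. No biological explanation was tested.

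The small gap between gene-end and other peaks might come from a difference between libraries that depends on peak abundance, since gene-end peaks are stronger. With trended offsets the gap was 0.0301, against 0.058 with TMM, and camera gave an adjusted p of 0.416 for this single set. The gap did not pass the threshold with TMM either, so the explanation cannot be told apart from no difference.

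The 4 libraries can be split into 2 and 2 in 3 ways. The genotype split called 4839 peaks, and the highest of the other splits called 4, so 1 of 3 splits gave as many. Each other split put 1 wild-type and 1 mutant library in each group, so the genotype difference widened its residual spread. Low counts there were built in and are no reference for the 4839. With 3 splits no share under 0.05 can be reached.

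Replicate 1 of each genotype carried signal at the Y-linked genes Uty and Ddx3y and replicate 2 did not. The replicate number and the Y-linked signal thus coincide in these libraries and are balanced over the genotypes.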
